A study of Glycine max with 12 samples.

How the data were processed

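Messenger RNA of developing soybean seed was measured in 12 libraries of genotype 93Y21, collected 35 days after flowering. Per the labels, 6 libraries came from seeds called nulls, 3 from transgenic event e15 and 3 from transgenic event e19, the events being separate transformation lines of a construct with the GmUBQ promoter. The sample titles mark both events as HOM and give the nulls another line code (33A) than the events (15A and 19A), and the relation of the nulls to either event is not given in the sources used here. Per the labels' protocols, total RNA was prepared with RNeasy columns, polyadenylated RNA was captured on oligo(dT) beads, libraries were made with a stranded mRNA kit and pooled, and single reads of 100 bp were sequenced. The labels number the replicates within a group but do not say whether they came from separate plants, so p-values measure the spread between these samples, which may be technical.

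The values analysed were estimated counts of reads per gene, as deposited by the authors in 1 table with a column per library. They were treated as estimates because 28752 of the 52872 genes had a value that was not whole in at least 1 library (tolerance 0.0005), as happens when reads that fit several genes are shared between them. The aligner, the counting program and the annotation are not given in the sources used here, beyond the tag W82a4v1 carried by the deposited table. Among the genes tested, 79.9% had a count that was not whole in some library, so levels of genes with near-identical copies are uncertain. Whether the counting used strand is not given either, so overlapping and antisense genes share that uncertainty. No column of the table was left out (0 columns).

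Counts were rounded to whole numbers. Genes with too few counts were removed with edgeR's filterByExpr on the groups, which kept 32115 genes of the 44782 with any count. Library sizes were scaled with TMM factors, and genes were tested with edgeR's robust quasi-likelihood test (edgeR 4.0.16, R 4.3.3) in 1 fit over all 12 libraries with a mean per group and no covariate. The contrasts were e15 against nulls, e19 against nulls, the mean of both events against nulls, and e15 against e19. A gene was called changed at a Benjamini-Hochberg false discovery rate of 0.05, and adjusted p-values below are from this test unless another is named. Standard errors of log2 fold changes were derived from the fold change and the F statistic. Such values can be too small where a group held few counts, so none is given there. Levels are in CPM, computed with the TMM-scaled library sizes and given as mean ± SD.

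Total counts ranged from 19207771 in e19 replicate 3 to 23276877 in null replicate 6. A floor of 3 counts per library corresponded to 0.130 CPM in the nulls, 0.137 CPM in e15 and 0.153 CPM in e19. A fold against a group with 0 counts was computed against this floor and is a lower bound. Where a group held few counts, the ratio is given with its exact 95% interval, and both floors and intervals cover counting error only. The test was tried on simulated counts with 200 changed genes per event. For e15 it recovered 43.5% of the changes of 1.5-fold, 66.7% of those of 2-fold and 95.4% of those of 4-fold over 31701 genes, with 6.21% false calls. For e19 it recovered 60.9%, 75.8% and 94.6% of these sizes over 31718 genes, with 4.29% false calls. The changed genes were drawn separately for each event, so differences between these shares need not reflect the events. All 6 nulls were simulated around 1 mean per gene, so the false calls do not cover nulls that differ in sets, as described below.

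Gene names were not used. The table identifies genes by Glyma identifiers alone, and 0 of these matched the RefSeq gene table of the assembly Glycine_max_v4.0, the 1 source of names used here. An annotation that pairs them with names was not used here. The gene lists fixed before the data were examined (sulfur and methionine metabolism, seed storage proteins, protease inhibitors, maturation, markers of other tissues or stages and others) rest on gene descriptions and were not analysed here, nor was the transgene's target, cystathionine gamma-synthase. The rule for genes named in the text was fixed before the data were examined: called genes with a mean of at least 5 CPM in either group and no overlap between the libraries of the groups, ranked by change and by abundance, with at most 2 risen and 2 fallen identifiers per comparison where no descriptions exist. Taking the first gene of each ranking was decided after the values were seen, as were the genes named as changed in both events, which had the smallest p in the mean of the events. The rule was met by 55 risen and 110 fallen genes in e15, by 12 and 6 in e19, and by 23 and 48 in e15 against e19.

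Chromosomes and the order of genes along them were read from the identifiers, which number genes along each chromosome, and no coordinates were used. A called gene had a neighbour when another called gene lay within 10 tested genes on either side. For called genes with whole counts, this window was counted among genes with whole counts alone. A cluster was at least 4 called genes, each at most 25 places after the one before among the tested genes of the chromosome. Both were compared with 1000 random placements of as many genes, drawn within 10 bins of mean expression. The numbers of called genes per chromosome were compared by Fisher's exact test with Benjamini-Hochberg adjustment over the chromosomes. The 20 and the 100 genes with the highest mean CPM were tested as sets with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and again with an estimated correlation. Shares of counts were compared by exact two-sided permutation tests. Principal components were computed from the 2000 genes of highest variance in log2 CPM. The chance overlap of the events through their shared nulls was simulated 10 times with unchanged groups.

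Alternatives fixed before the data were examined were RLE factors, library totals alone, totals without the 20 most abundant genes, no filter, at least 10 counts in every library, DESeq2 1.42.0, limma-voom, a fit of the compared groups alone, the replicate number as a block, each library left out in turn, a fold of at least 2, and a division of the nulls between the events. Fits with nulls 1 to 3 and nulls 4 to 6 as separate subgroups, and with all libraries thinned to the smallest total, were added after seeing the data, as were the analyses of chromosome position, of genes detected in one group and not in another, and of the most abundant genes.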

Results

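The series measured messenger RNA in developing soybean seed to compare 2 transgenic events, e15 and e19, with null seeds. Its title concerns a deletion variant of GmCGS2, a cystathionine gamma-synthase, and genes for proteins rich in sulfur amino acids. Cystathionine gamma-synthase catalyses the first committed step of methionine synthesis in plants. The 6 null libraries held 21357512 to 23276877 counts, the 3 of e15 21988821 to 22849075 and the 3 of e19 19207771 to 21900491. The level of the targeted gene could not be checked against the labels, because the files used here do not pair the identifiers with names, and genes are therefore given by identifier. No pair of libraries within a group was alike within counting noise, since the squared differences between replicates were at least 1.76 times those of counting alone.

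The 6 nulls fell into 2 sets by replicate number. On the first principal component, which held 28.8% of the variance, nulls 1 to 3 lay between -29.3 and -27.7 and nulls 4 to 6 between 12.4 and 13.4, while the second component (18.4%) set e15 apart. Replicate 3 of e19 lay at -7.01 on the first component, against 16.74 and 14.05 for replicates 1 and 2, and had the lowest total of all libraries. Pairwise correlations of log2 CPM across genes were 0.988 to 0.989 within nulls 1 to 3, 0.986 to 0.987 within nulls 4 to 6 and 0.975 to 0.978 between these sets. Between nulls 4 to 6 and nulls 1 to 3, 1448 genes were higher and 1631 lower, of which 602 differed at least 2-fold. With library totals alone in place of TMM scaling, 514 genes were higher and 7009 lower, a share of higher genes of 6.83% against 47.0% with TMM, and a fit of the 6 nulls alone called 5004 genes. The labels give both sets the same description, and their difference enters the spread against which the events were tested.

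**Figure D1:**
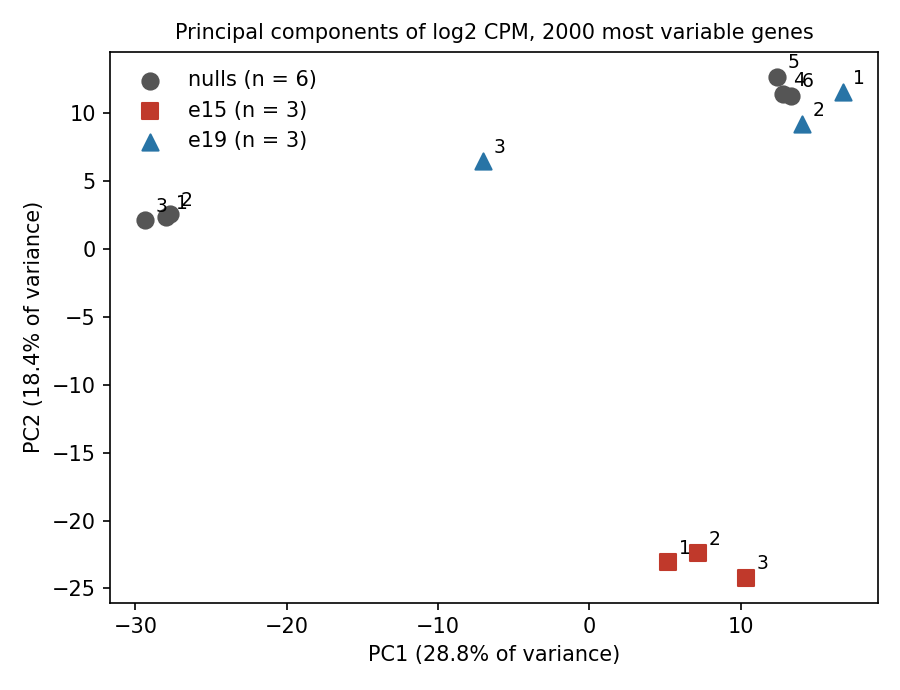
First and second principal components of log2 CPM of the 12 libraries, with 1 point per library and the percent of variance on each axis. Nulls 1 to 3 lie at -29.3 to -27.7 on the first component, apart from nulls 4 to 6 at 12.4 to 13.4, and e15 lies at -24.2 to -22.4 on the second, with e19 replicate 3 at -7.01 on the first, apart from the other e19 libraries.

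In e15, 83 genes rose and 159 fell against the nulls. The risen genes had a median log2 change of 0.96 in e15 and of 0.20 in e19, and the fallen genes a median of -0.56 in e15 and -0.10 in e19. The medians in e15 were the same with the 3 risen and 4 fallen genes that had 0 counts in 1 of the groups set to their bounds. At least 2-fold changes were seen for 39 risen and 39 fallen genes. At least 10 counts in every e15 library and at most 3 in every null were found for 8 genes, the opposite was found for 6 genes, and all 14 were called.

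Glyma.17G173200 had the largest fitted rise in e15, a rank that depends on the prior count because the nulls held no counts of it. It had 0 counts in the nulls, 7.07 ± 0.553 CPM in e15 (n = 3) and 2 counts in the 3 e19 libraries together. Its e15 level was at least 54.3-fold higher than the floor of the nulls (adjusted p = 1.51e-10). The most abundant risen gene was Glyma.16G208900, at 4579 ± 296 CPM in the nulls (n = 6) and 8938 ± 592 CPM in e15 (n = 3), with a log2 change of 0.96 ± 0.10 (SE, adjusted p = 1.97e-06). The ranking of the falls also depends on the prior count, since 4 fallen genes had 0 counts in 1 of the groups. The largest fitted fall was that of Glyma.06G273700, from 7.70 ± 0.745 CPM in the nulls to 2 counts in the e15 libraries together. The ratio of nulls to e15 was 254, with a counting interval of 70.1 to 2100, and e19 had 7.99 ± 1.13 CPM. The most abundant fallen gene, Glyma.11G133600, went from 328 ± 37.2 CPM to 252 ± 5.69 CPM, a log2 change of -0.38 ± 0.09 (SE, adjusted p = 0.0398). Its null level mixed 295 ± 7.04 CPM in nulls 1 to 3 and 361 ± 9.86 CPM in nulls 4 to 6 (adjusted p = 0.00576), against which its log2 change in e15 was -0.23 and -0.52. That call was lost without null 4, 5 or 6 (adjusted p = 0.0666, 0.0603 and 0.0693) and without e15 replicate 1, 2 or 3 (0.184, 0.123 and 0.308), within a range of 1.54e-05 to 0.308 over the alternatives. Of these genes Glyma.17G173200 had whole counts in all libraries, and the others had counts that were not whole in some.

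The number of genes called in e15 was 106 without e15 replicate 1 (49 risen and 57 fallen), 129 without replicate 2 (50 and 79) and 82 without replicate 3 (41 and 41), so that the excess of fallen genes was absent without replicate 3. With library totals alone 50 genes rose and 143 fell. The number was 376 against nulls 4 to 6 and 2676 against nulls 1 to 3, and 182 and 240 of the 242 genes were also called there with the same sign.

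In e19, 15 genes rose and 9 fell against the nulls, with a median log2 change of 1.39 for the risen and -1.27 for the fallen genes. In e15 the same genes had medians of 0.82 and -0.96. At least 2-fold changes were seen for 17 of the 24 genes. Glyma.20G076400 had the largest rise, from 0.0366 ± 0.0344 CPM in the nulls (5 counts in all) to 8.02 ± 1.29 CPM in e19 (n = 3). Its fitted log2 change was 7.59 (adjusted p = 4.46e-14). The ratio of its counts was 223, with a counting interval of 95.03 to 691. Glyma.16G208900, the most abundant risen gene, reached 9094 ± 1479 CPM in e19, a log2 change of 0.99 ± 0.10 (SE, adjusted p = 4.97e-06). Among the genes that met the naming rule, Glyma.04G194900 had the largest fall, from 62.7 ± 2.45 CPM in the nulls to 18.2 ± 0.457 CPM in e19, while e15 had 64.4 ± 1.46 CPM. Its log2 change in e19 was -1.79 ± 0.06 (SE, adjusted p = 7.00e-14). Glyma.09G158700, the most abundant fallen gene, went from 241 ± 14.1 CPM to 99.9 ± 21.9 CPM, a log2 change of -1.27 ± 0.12 (SE, adjusted p = 8.91e-05). The next tested gene on chromosome 9 rose, with log2 changes of 1.52 in e15 and 1.29 in e19. Whether reads were shared between these 2 genes was not tested. Glyma.09G158700 and Glyma.04G194900 had counts that were not whole in each of the 12 libraries. The number of genes called in e19 was 81 against nulls 4 to 6 and 2322 against nulls 1 to 3, where 23 and 24 of the 24 genes were also called with the same sign. Without e19 replicate 3 it was 23.

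Both events called 16 genes in the same direction, 10 risen and 6 fallen, and 3 in opposite directions. All nulls carry a line code that neither event has. A change common to the events therefore cannot be told apart from a trait of the null line. The 10 risen genes had a median log2 change of 1.28 in e15 and 1.21 in e19, and the 6 fallen genes -1.37 and -1.23. Between the events, 1 of the 10 risen and 0 of the 6 fallen genes differed in edgeR's test of e15 against e19. Glyma.20G076400 was at 9.41 ± 0.477 CPM in e15, 261 times the nulls with a counting interval of 111 to 808, and was the 1 gene with at least 10 counts in all 6 event libraries and at most 3 in all 6 nulls. The opposite was found for 1 gene. Glyma.09G235400 rose from 45.1 ± 1.80 CPM in the nulls to 219 ± 3.98 CPM in e15 and 118 ± 18.6 CPM in e19, which is 4.86-fold and 2.62-fold. Its log2 level was higher in e15 than in e19 by 0.89 ± 0.09 (SE, adjusted p = 2.39e-06). Glyma.09G158700 was at 87.4 ± 11.9 CPM in e15, a log2 change of -1.46 ± 0.12 (SE, adjusted p = 5.48e-06). Glyma.13G296900 went from 13.6 ± 1.01 CPM in the nulls to 7.01 ± 0.486 CPM in e15 and 5.98 ± 0.0563 CPM in e19, log2 changes of -0.96 and -1.19. Glyma.16G208900 differed between the events by -0.02 on the log2 scale, with a 95% interval of -0.25 to 0.20. Counts of Glyma.09G158700, Glyma.09G235400 and Glyma.13G296900 were not whole in each of the 12 libraries, those of Glyma.16G208900 in 5, and Glyma.20G076400 had whole counts.

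Because both comparisons used the same nulls, unchanged groups were simulated against them 10 times. These called a mean of 1.1 genes for e15 and 0.5 for e19 and shared a mean of 0.1 and at most 1, and lists that short give no chance value for lists of 242 and 24 genes. Independent lists of these lengths would share 0.0388 risen and 0.0446 fallen genes. With nulls 1 to 3 used for e15 and nulls 4 to 6 for e19, 13 genes rose and 10 fell in both, and 29 changed in opposite directions, where independent lists give 1.69 and 1.63. With the nulls exchanged, 17 rose and 42 fell in both and 67 went in opposite directions, against 3.80 and 9.78. These chance values hold for genes risen or fallen in both, and none was computed for opposite directions. In both divisions of the nulls more genes changed in opposite directions (29 and 67) than in the same direction (23 and 59). A gene that differs between the null sets can be called in opposite directions there though both events are alike. These numbers therefore do not show that the events disagree. With the same nulls for both events, 3 genes went in opposite directions and 16 in the same. With the nulls as 2 subgroups in 1 fit these were 4 and 68. The mean of both events differed from the nulls for 36 risen and 46 fallen genes. With library totals alone these numbers were 23 and 62, a share of risen genes of 27.1% against 43.9%, and under that scaling the median log2 change of all genes was -0.10 in e15, -0.13 in e19 and -0.11 in the mean of the events. The count of 82 was 53 without null 1 and 54 without e15 replicate 3.

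**Figure D2:**
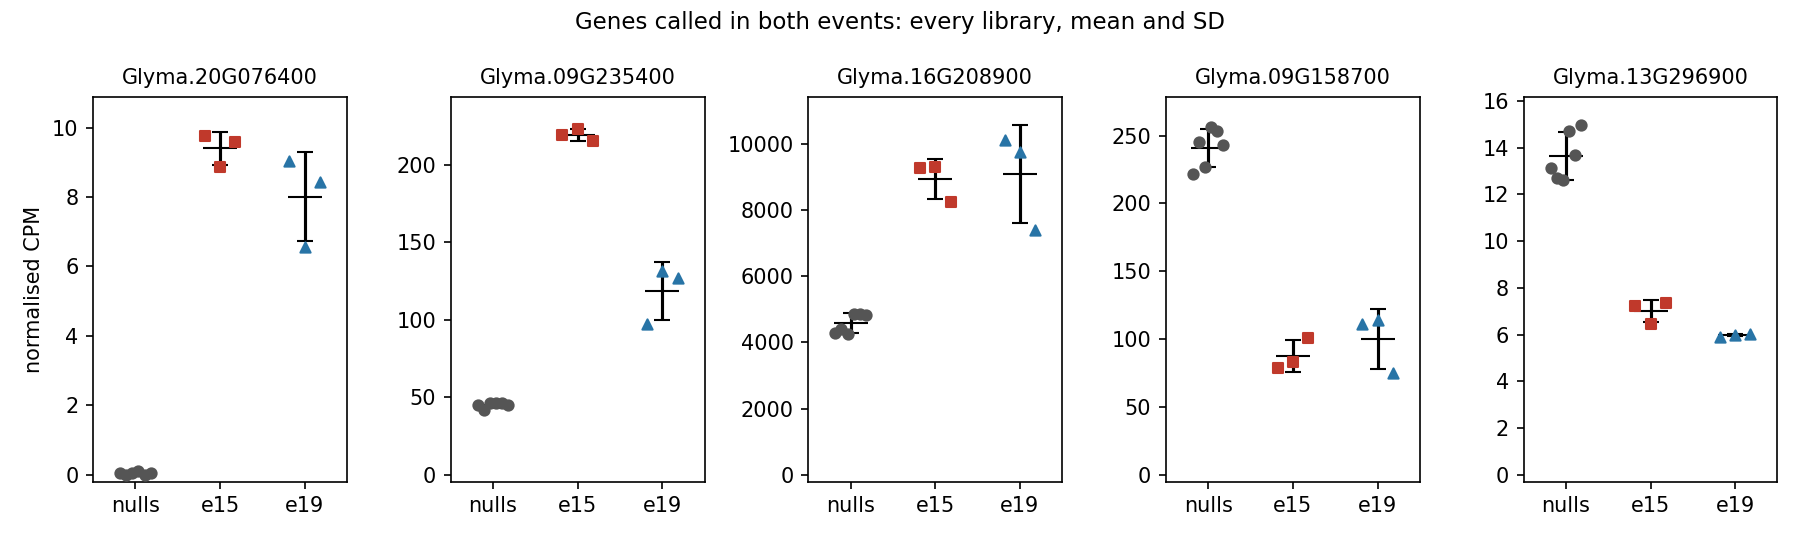
CPM of 5 named genes in each of the 12 libraries, with 1 point per library and the mean and SD of each group. Glyma.20G076400 stands at 9.41 CPM in e15 and 8.02 CPM in e19 against 0.0366 CPM in the nulls, and Glyma.09G235400 at 219 CPM in e15, 118 CPM in e19 and 45.1 CPM in the nulls.

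**Figure D3:**
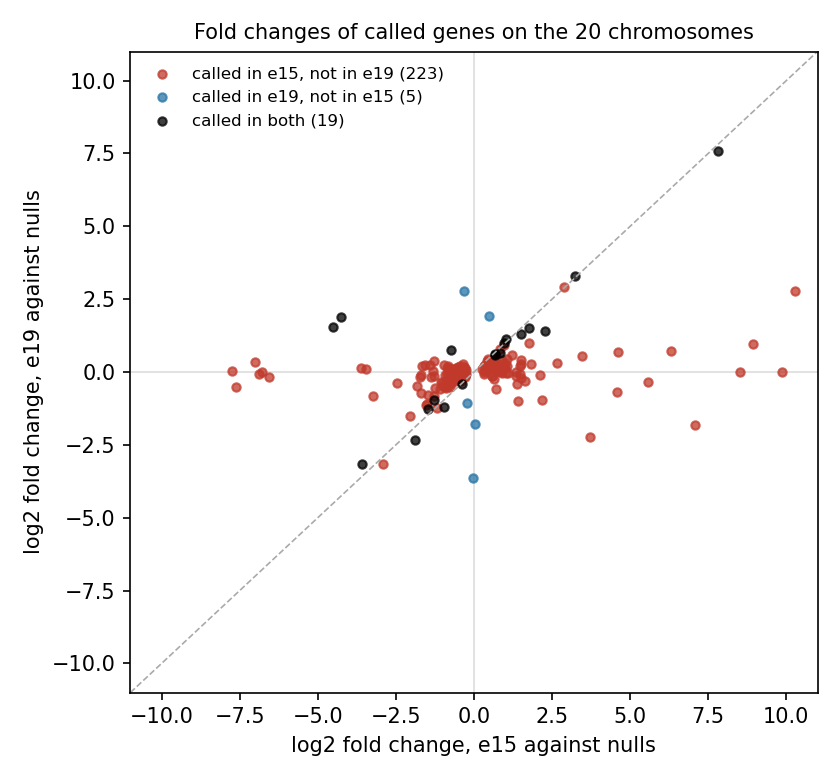
Fitted log2 fold changes of e15 (x axis) and e19 (y axis) against the same nulls, with 1 point per called gene, colours for the event in which it was called and a dashed line of equal change. Called in both events were 19 genes, 16 with the same sign, while 223 were called in e15 and not in e19, and 5 in e19 and not in e15.

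Set against each other, e15 was higher than e19 for 35 genes and lower for 61, and 48 of these 96 genes differed at least 2-fold. Of the 242 genes called in e15 against the nulls, 79 also differed from e19 in the same direction, 29 of them higher and 50 lower. At least 10 counts in every library of one event and at most 3 in every library of the other were found for 10 genes present in e15 and 6 present in e19. Glyma.05G236500 had 5.31 ± 0.250 CPM in e15 and 0 counts in e19 and in the nulls, at least 34.8-fold above the floor of e19 (adjusted p = 1.50e-07). Glyma.17G171400 had 9.91 ± 1.19 CPM in e15 and 2 counts in e19, a ratio of 293 with a counting interval of 80.9 to 2427 (adjusted p = 7.42e-12). Lower in e15 was Glyma.06G273700, given above, with an adjusted p of 4.48e-12. Glyma.06G243500 was at 3.22 ± 0.681 CPM in the nulls, 0.140 ± 0.138 CPM in e15 and 9.52 ± 3.20 CPM in e19. Its log2 change was -4.51 in e15 and 1.56 in e19 (adjusted p = 0.000583 and 0.0299) and -6.06 between the events (adjusted p = 1.87e-05). Counts were not whole in 2 libraries for Glyma.05G236500, in 7 for Glyma.17G171400 and in 11 for Glyma.06G243500.

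The genes called in e15 lay close to one another on the chromosomes. Another called gene lay within 10 tested genes for 33.9% of them, while random placements gave a mean of 13.95% and a highest value of 26.4% (permutation p = 0.001, the smallest that 1000 placements can give). They formed 12 clusters with 65 genes on 8 chromosomes, against a mean of 0.983 clusters and at most 5 in random placements. The cluster with the most calls that differed from e19 held 7 genes at places 1142 to 1167 of the 1609 tested genes of chromosome 17, 5 risen and 2 fallen. Chromosome 14 held 23 called genes where 9.40 were predicted by its size (adjusted p = 0.00156, Fisher's exact test), and chromosome 17 held 23 against 12.2 (adjusted p = 0.0429). That test treats called genes as independent, which their clusters argue against, so both p-values may be too small. In e15 against e19, 34.4% of the called genes had a neighbour, with a mean of 5.75% and a highest value of 16.7% in random placements. Of the genes called in e19, 8.33% had a neighbour (permutation p = 0.184), where random placements gave a mean of 1.63% and at most 16.7%. These were 24 genes, too few to decide whether they cluster. Of as many top genes of e19 as were called in e15, 10.4% had a neighbour (permutation p = 0.873), against a random mean of 13.8%. Most of those top genes were not called in e19.

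**Figure D4:**
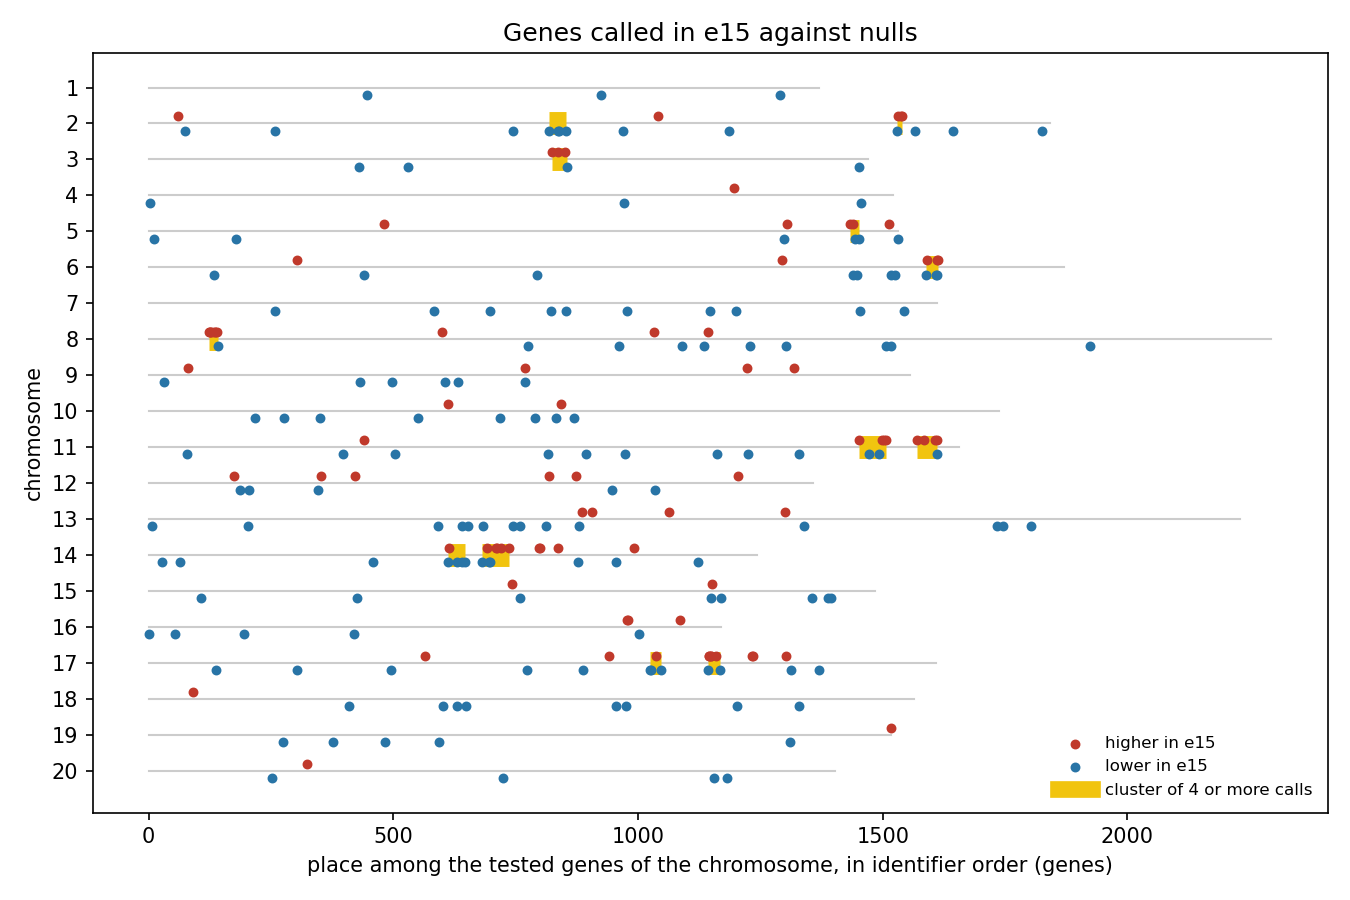
Genes called in e15 against the nulls, drawn by chromosome (rows) and place among the tested genes of that chromosome (x axis, in genes), with red above the line for higher, blue under it for lower and yellow bars for clusters. The 12 clusters of e15 calls lie on 8 chromosomes, including places 681 to 736 of chromosome 14 and places 1142 to 1167 of chromosome 17.

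The 20 most abundant genes took 41.5 ± 2.67% of the counts in the nulls (n = 6), 44.9 ± 1.01% in e15 (n = 3) and 45.4 ± 1.93% in e19 (n = 3). Exact two-sided permutation tests gave p = 0.0714 for e15 and 0.0952 for e19, both 0.178 after adjustment over 16 tests. The share was 39.1 ± 0.664% in nulls 1 to 3 and 43.9 ± 0.375% in nulls 4 to 6, so that the difference between these sets was larger than that of either event from all nulls. Of the 20 genes, 2 rose and 0 fell in e15, and likewise in e19, with a median log2 change of 0.17 and 0.23. Higher than in the nulls were 15 of the 20 in e15 and all 20 in e19, and with library totals alone these numbers were 13 and 12. The set test gave an adjusted p of 2.15e-07 for e15 and 2.19e-11 for e19 with the preset correlation, but an adjusted p = 0.341 in both with an estimated correlation. In the fit with the nulls as 2 subgroups, 6 of the 20 rose in e15 and 7 in e19 against all nulls. In that fit, against nulls 4 to 6, 3 of the 20 rose in each event and 0 fell, with medians of 0.00 and 0.06, and against nulls 1 to 3, 12 rose in each event, with medians of 0.38 and 0.44.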

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

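The tests of gene position and of equal depth, and the choice of e19 replicate 3 among the libraries left out, were made after the results were seen. Leaving out each library and the counts over other groupings of the libraries were planned. Of the 19 sets of null values tested (library measures and named genes), 0 held a library far from the others. The search looked for a lone library among the nulls, so it says nothing on their split into sets or on the event libraries. Values of Glyma.17G173200 and Glyma.05G236500, with 0 counts in every null, could not show such a library.

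The events differed from each other for 96 genes in edgeR's test of e15 against e19, although both carry the same construct per the labels. The fitted log2 difference, e15 over e19, was 9.87 for Glyma.05G236500, 7.97 for Glyma.17G171400, 7.48 for Glyma.17G173200, 1.82 for Glyma.04G194900 and 0.89 for Glyma.09G235400. It was -6.06 for Glyma.06G243500 and -7.79 for Glyma.06G273700. The fitted values of the genes at 0 to 3 counts in 1 event depend on the prior count and are no bounds. The 6 libraries of the events make 10 groupings, too few for a share under 0.05: the real one gave 145 genes in a fit of these libraries alone and the highest other gave 4.

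Clustered calls in e15 were the first pattern weighed. The tables argue against the structure of the nulls as its whole cause, since 34.4% of the calls of e15 against e19, which does not use the nulls' levels, had a neighbour, above the 16.7% that random placements reached. Shared reads, as far as counts that are not whole show them, were examined in the 46 called genes with whole counts in every library. Of these, 28.3% had a neighbour (permutation p = 0.030), where random placements gave a mean of 13.1% and at most 34.8%, which argues only weakly against shared reads. Neighbours were counted here among genes with whole counts alone, so the window was wider than for all tested genes. This share is therefore not comparable with the 34.4% above. A local effect of 1 insertion is argued against by clusters on 8 chromosomes, more than the 5 clusters that chance reached. Called genes inside the clusters differed from e19 in 41 of 65 cases and those outside in 38 of 177, but the former also had larger changes in e15 (median absolute log2 1.29 against 0.56), so this difference in calls decides nothing. Chromosome segments in which the e15 seeds differ genetically from the other libraries are a candidate explanation, which was not tested on sequence, and a variant against the reference that changes read mapping stays open beside it.

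The larger number of calls in e15 (242) than in e19 (24) was the second pattern. The gap depended on the threshold. An unadjusted p under 0.05 in edgeR's test, which admits many false calls, was reached by 2927 genes in e15 and 2262 in e19. Without e19 replicate 3, which lay apart from the other e19 libraries, e19 gave 23 genes and e15 205. That fit left e19 with fewer libraries than e15, so it cannot by itself rule out that library as the cause. With 1 of its own libraries left out, e15 still gave 82 to 129 genes, in fits that kept e19 replicate 3. With all libraries thinned to the smallest total e19 gave 22 genes and e15 206, so the lower depth of e19 does not account for the excess. The size of the excess depended on the e15 libraries, since e15 gave 106, 129 and 82 genes without its replicate 1, 2 or 3 and e19 gave 26, 24 and 24 in the same fits. Outside the clusters e15 still had 177 called genes, so the clusters alone do not account for it either. A real difference between the events may remain, since e15 gave 376 and e19 gave 81 genes against nulls 4 to 6, but 2676 and 2322 against nulls 1 to 3, and the number of calls itself was not compared by a test.

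For e15 against the nulls, 2 of the 84 groupings of these 9 libraries gave as many genes as the real one (207 in a fit of these libraries alone), and the other one set nulls 1 to 3 apart and gave 4022, which points to a structure of the nulls. For e19, 3 of 84 groupings reached the real value of 23, the others setting nulls 1 to 3 apart (4005) and nulls 4 to 6 apart (72). For both events together against the nulls, 3 of 100 groupings drawn reached the real value of 31, and both others (117 and 58) kept nulls 1 to 3 on one side. That value comes from a fit with 1 mean for both events, where the main fit called 82 genes. These shares are under 0.05, but they exclude chance only for libraries that could be exchanged, which the null sets argue against. Of the groupings of 9 libraries, 3 keep the event and both null sets whole, too few for a share under 0.05, and e19 gave the lowest count of its 3. Within the null sets, e15 gave 376 genes against nulls 4 to 6 and 2676 against nulls 1 to 3, e19 gave 81 and 2322, and the mean of both gave 156 and 3503.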

How the results depend on the processing

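The fits with separate null sets and with thinned libraries were chosen after the results were seen, and the rest were planned. No named gene changed direction. Of the 16 results for named genes, 15 kept their direction and their side of the threshold under all 22 to 25 settings run for each. The exception was Glyma.11G133600 in e15, whose log2 change stayed between -0.52 and -0.23 and which lost its call without null 4, 5 or 6 or any e15 library. RLE factors, library totals alone, totals without the 20 most abundant genes, both other filters, limma-voom and thinning kept the total calls of each event comparison within 1.5 times, although the risen genes of e15 went from 83 to 50 with library totals alone, and calls between the null sets from 3079 to 7523. The side with more calls changed for the mean of the events (36 risen and 46 fallen, 42 and 39 with limma-voom) and for e15 against e19 (35 and 61, 26 and 22 at 2-fold or more), and e15 had 41 and 41 without its replicate 3 (83 and 159 with it). For genes called in both events (10 and 6) it changed against nulls 4 to 6 (15 and 30), against nulls 1 to 3 (605 and 681), with the nulls exchanged (17 and 42) and with the replicate block (530 and 584). DESeq2 moved 1 count beyond 1.5 times, giving 157 genes for the mean of the events, and the fit of the compared groups alone moved e15 against e19 to 145. A fold of at least 2 left 78 genes in e15, 29 in the mean of the events, 48 in e15 against e19 and 9 in both events, by construction.

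With the nulls as 2 subgroups the counts were 888 (e15), 148 (e19), 723 (mean of events), 341 (e15 against e19) and 68 (both events), where the spread between the null sets no longer enters the error, and 241 of the 242 e15 genes and 24 of the 24 e19 genes were among them. Against nulls 4 to 6 in the same fit the counts were 376, 81, 156 and 45 (both events), and against nulls 1 to 3 they were 2676, 2322, 3503 and 1286. This fit uses 1 spread per gene for all groups, although the groups differed in it. Squared differences between replicates were 1.76 to 3.41 times those of counting within the null sets, 4.44 to 7.02 times in e15 and 6.92 to 10.4 times in e19. Counts from this fit may therefore be too high. Its contrasts with all nulls use the mean of the 2 sets, so a gene can be called where an event differs from 1 set alone. For e19, the calls against nulls 1 to 3 and against nulls 4 to 6 shared 28 genes with the same sign. With nulls 4 to 6 used for e15 and nulls 1 to 3 for e19, 59 genes were called in both. Leaving out 1 library gave 82 to 268 genes in e15, 17 to 26 in e19, 53 to 107 in the mean of the events, 67 to 101 in e15 against e19 and 12 to 16 in both. The lowest e15 count came without e15 replicate 3, and 106 and 129 came without replicates 1 and 2. The mean of the events had 53 without null 1 and 54 without e15 replicate 3.

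With the replicate number as a block, 2350 genes were called in e15, 1945 in e19, 3074 in the mean of the events, 292 in e15 against e19 and 1114 in both. The numbers share no more than a number: the 9 correlations between libraries of the same number ran from -0.05 to 0.07, and 3 of 9 libraries correlated best with their own number. Because nulls 4 to 6 have numbers that the events lack, this fit sets the events against nulls 1 to 3 by construction. The alternatives planned for the gene lists and for the transgene's target were not run, because no identifier matched a name. Depth sets the floor of 3 counts per library, 0.130 CPM in the nulls. Of simulated 1.5-fold changes 43.5% were recovered in e15 and 60.9% in e19, in separate draws of genes, so the difference need not reflect the events.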

Other observations

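All tests in this part were chosen after the data were seen. The most abundant transcripts and transcripts seen in one set of libraries alone also distinguished the null sets. Of the 20 most abundant genes, 13 were higher in nulls 4 to 6 than in nulls 1 to 3 and 0 were lower, with a median log2 difference of 0.31. Of the 100 most abundant, 46 were higher and 3 lower. At least 10 counts in each of nulls 4 to 6 and at most 3 in each of nulls 1 to 3 were found for 3 genes, and the opposite for 15 genes, with 17 of these 18 called. In nulls 1 to 3, 34071 ± 40.4 genes had at least 5 counts (n = 3), against 33421 ± 17.4 in nulls 4 to 6 (n = 3), and the exact two-sided permutation p was 0.1, the smallest this design allows.

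Of the 100 most abundant genes, 3 rose and 0 fell in each event against all nulls, with median log2 changes of 0.07 in e15 and 0.10 in e19 that became -0.02 in both with library totals alone. Set tests gave an adjusted p of 7.04e-05 and 2.59e-10 with the preset correlation, and adjusted p = 0.524 and 0.341 with an estimated correlation. These sets were chosen by abundance in the same libraries.

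The difference between nulls 1 to 3 and nulls 4 to 6 was the third pattern weighed. Depth is argued against by 2843 genes that still differed with every library thinned to the smallest total. A few abundant genes taking more of the counts are argued against as the whole cause, since with library totals alone, where such genes would lower the rest, 485 genes outside the 100 most abundant were higher in nulls 4 to 6, 137 of them at least 2-fold, against 376 false calls allowed among all 7523. For genetic differences in chromosome segments, the top 242 genes showed no excess of neighbours. Of these, 11.6% had a neighbour, where random placements gave a mean of 14.1% and at most 23.1% (permutation p = 0.814). That covers only the top of the 3079 genes that differed, so this explanation stays open. A batch of seed, of seed stage or of library preparation may account for the difference between the null sets and also stays open, as the labels name none. No other biological explanation was tested, as the labels describe both sets alike.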
